A study of Mus musculus with 37 samples.

How the data were processed

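RNA from 37 cultures of mouse primary astrocytes was measured on 37 one-colour arrays. Per the labels, the cells came from newborn mice of the strains 129S4/SvJae (129) and C57BL/6J (B6), of both sexes, and were stably transfected with a plasmid that carried Cdca7l or with the empty vector. The labels give a high RNA quality score for each sample and name an amplification kit that starts from a small amount of total RNA. The deposited table holds log2 expression values for 45101 probe sets. Per the submitters' processing notes, the authors used GCRMA and Partek 6.5; whether the arrays were normalized together is not given in the sources used here. The values ran from 1.17 to 15.3, so they were used as deposited, with no further transformation.

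Gene names came from the platform annotation, checked through Entrez IDs against the assembly GRCm38.p6, which was used for names and neighbours alone. In the whole table, 34958 probe sets carried 1 gene symbol, 932 carried several and 9211 carried none; 34754 of the probe sets with 1 symbol matched by Entrez ID. No gene was named from a probe set with several symbols. The median of the table, 3.189 on the log2 scale, served as the background level. A probe set was tested when it exceeded that level on at least 4 arrays; 64 control probe sets were left out, 19458 probe sets did not pass, and 25579 were tested. Where a probe set stayed at or below the background level on every array of the dimmer groups, the fold is a lower bound, computed against the higher of that level and the measured value and written as "at least". Where a part of those arrays exceeded the level, the fitted difference is given, and beside it, for genes mostly at background, that with lower values raised to the level. Log2 values have no count depth, so the number of arrays limits the precision.

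All 37 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3, with a mean for each of the 8 groups, 29 residual degrees of freedom and empirical Bayes moderation. There were 11 comparisons. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values in the text are from limma unless another test is named. Gene lists, 17 on pathways and 8 on cell types, were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, that with the highest mean, with adjustment over the 25 lists. Camera with an estimated correlation and fry, which asks whether a list moves on balance without comparing it with other genes, were run beside it. The comparisons, the tests, the filter, the lists and the rule for naming genes were chosen before the data were examined. That rule took the 10 genes with the largest positive and the 10 with the largest negative difference past the threshold, the 5 with the smallest p where fewer passed, Cdca7l, Xist and the Y-linked genes, and up to 4 members of each list with a call. Genes named outside it, as members of lists that moved or as calls of an alternative, were chosen after their values were seen. One gene among the largest strain differences is not reported here, and values of Xist and the Y-linked genes are given for a part of the comparisons. A list score is the mean over the members of their values, each centred on its mean over all arrays.

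The design text describes the cultures as independent isolates, and the array labels give each a clone number with a number in parentheses. Within a strain and sex, Cdca7l and vector arrays share some clone labels. Deviations from the group means of same-labelled arrays correlated at 0.432 to 0.775 over 3 pairs in B6 females and at 0.376 to 0.572 over 4 pairs in B6 males, so the labels were taken as pairs there. Of 4 pairs each, the lowest reached 0.061 in 129 females and -0.0887 in 129 males, while the others lay at 0.416 to 0.716 and 0.472 to 0.623; as not every pair deviated together, those arrays were taken to share a label only. The main fit and the exact tests of Cdca7l used no pairs in any group. Blocks on the clone label used it in every strain and sex. The correlation within a clone label was 0.409 over all arrays. A fit without pairs can therefore overstate the spread of Cdca7l minus vector differences. Alternatives covered the variance prior, the filter, another normalization, array weights, blocks on the clone label and its parts, 1 probe set per gene, fits of the compared groups alone and each array left out in turn.

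The fit was tested on simulated data with the measured means and spreads of 25579 probe sets. In each comparison 67 of them were given a change of 1 on the log2 scale, 67 a change of 2 and 66 a change of 3. Arrays were simulated as independent, without shared clone labels. So many true changes also ease the adjusted threshold, so the shares may be too high for comparisons with few changes. For the averaged Cdca7l effect, 62.7% of changes of 1 on the log2 scale and 94% of changes of 2 were called in the right direction. For the effect in B6 females these shares were 25.4% and 61.2%, and for the strain difference in vector cells 44.8% and 86.6%. For the differences of the Cdca7l effect they were lower: 10.4% and 52.2% between sexes, 20.9% and 58.2% between strains, and 4.48% and 14.9% for strain by sex. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.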

Results

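Expression was measured in primary mouse astrocytes that carried a Cdca7l plasmid or the empty vector, in males and females of the strains 129S4/SvJae (129) and C57BL/6J (B6). The Cdca7l groups held 4 arrays of 129 females, 5 of 129 males, 4 of B6 females and 5 of B6 males, and the vector groups held 4, 5, 5 and 5 in that order. The upper quartile of the log2 values lay between 9.04 and 9.51 on 36 arrays and at 8.36 on the array of 129 female vector 1(3). The array labelled B6 female vector 5.1(1) carried Xist at 2.40, where the other 16 female arrays lay between 10.71 and 12.20, and Eif2s3y at 11.91, inside the male range. Both arrays stayed in the comparisons. Without 129 female vector 1(3), 8 of the 87 list calls were lost and 18 gained, and without the array labelled B6 female vector 5.1(1) 7 were lost and 4 gained. Of the 87 calls, 37 were kept with each array of their comparison left out in turn.

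RNA of Cdca7l, which encodes a nuclear protein that binds MYC, was far more abundant in cells with its plasmid in every strain and sex, and Dnah11, which encodes a heavy chain of ciliary dynein, was higher with it. Averaged over the 4 strain and sex groups, Cdca7l rose by 4.62 ± 0.484 (SE, log2), a 24.5-fold difference with adjusted p = 1.25e-06. Dnah11 rose by 4.73 ± 0.461, a 26.5-fold difference with adjusted p = 4.53e-07. With a fixed replicate block Dnah11 still passed (adjusted p = 0.00976), while Cdca7l lay at 4.61 ± 0.624 with unadjusted p = 5.38e-06 and adjusted p = 0.0688. The annotated spans of both genes overlap in GRCm38.p6. The labels give neither the species of the insert nor whether the Cdca7l probe set reads it. No other probe set passed in the averaged comparison, in which 324 had an unadjusted p under 0.05 where 1279 would by chance alone. The next smallest p-values belonged to Pim2, a serine/threonine kinase, at 0.80 ± 0.271, Iqcb1, a ciliary protein, at 0.52 ± 0.18, and 1700110K17Rik at 0.30 ± 0.103, each with adjusted p = 0.999.

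Within groups, mean Cdca7l was 12.36 ± 1.48 (SD, n = 4) with the plasmid and 7.62 ± 2.81 (SD, n = 4) with the vector in 129 females, and 12.40 ± 0.401 (SD, n = 5) against 8.53 ± 0.559 (SD, n = 5) in 129 males. In B6 females it was 13.07 ± 0.969 (SD, n = 4) against 7.98 ± 0.795 (SD, n = 5), and in B6 males 12.46 ± 1.71 (SD, n = 5) against 7.71 ± 2.04 (SD, n = 5). The differences amounted to 26.9-, 14.6-, 34.2- and 26.8-fold. In 129 females the log2 difference was 3.61 without 129 female vector 1(3), 5.69 without 129 female vector 4(1) and 4.10 without 129 female Cdca7l 2(3), and in B6 males it was 3.84 without B6 male vector 3(5). In each group the lowest Cdca7l array exceeded the highest vector array. Exact two-sided permutation tests gave p = 0.0286 in 129 females, the smallest this group size allows, and p = 0.00794 in each of the other groups. Adjusted over its own list alone, Cdca7l passed in each of the 4 groups.

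**Figure D1:**
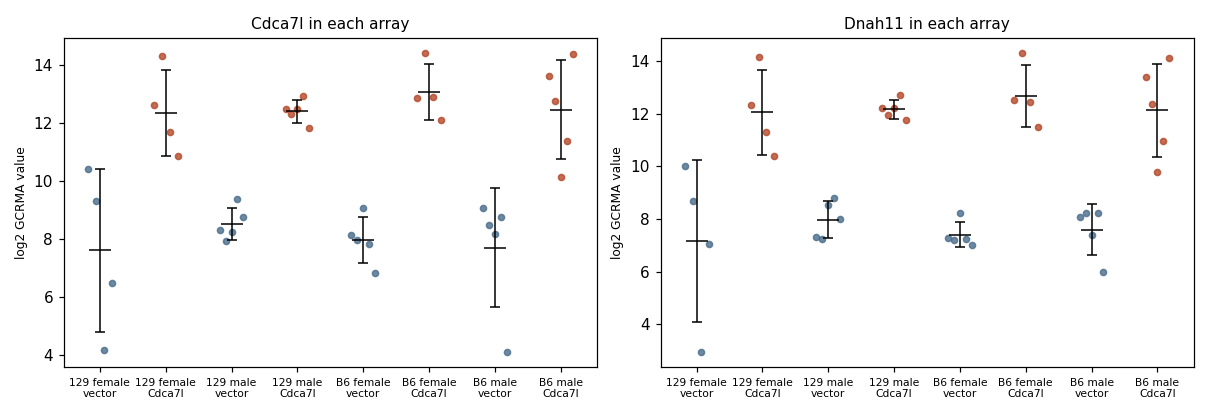
Log2 GCRMA values of Cdca7l (left) and Dnah11 (right) on each array by strain, sex and plasmid; points are arrays, and the bar with whiskers is the group mean and SD. Mean Cdca7l lies at 12.36 to 13.07 with the plasmid and at 7.62 to 8.53 with the vector, and Dnah11 follows it.

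The list of Cdca7l, the MYC network and its partners rose with Cdca7l in the averaged comparison: 17 of 20 measured members were higher, with a median of 0.12 (log2, camera adjusted p = 1.6e-05; adjusted p = 0.00312 with an estimated correlation). One member, Cdca7l itself, passed both over all genes and adjusted over the list alone. Without Cdca7l, 16 of 19 members were higher, with a median of 0.09 and adjusted p = 0.0532 with an estimated correlation (fry adjusted p = 0.101). Maob, a monoamine oxidase, lay at 0.78 ± 0.369, the chromatin regulator Kmt2a at 0.40 ± 0.224 and Psip1, a chromatin-bound protein, at 0.25 ± 0.154, none past the threshold.

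Camera called 10 more lists in the averaged comparison. Members lay higher for G2/M-phase genes (26 of 27, median 0.33), p53 target genes (18 of 20, 0.08), interferon response genes (24 of 26, 0.26), NF-kB and inflammatory genes (15 of 20, 0.16), antigen presentation genes (10 of 10, 0.27) and ependymal and choroid plexus markers (9 of 10, 0.63). They lay lower for MYC target genes (12 of 36 positive, median -0.05), cholesterol synthesis genes (3 of 16, -0.13), extracellular matrix and TGF-beta response genes (3 of 23, -0.13) and microglia and macrophage markers (1 of 14, -0.86). With an estimated correlation these 10 calls were lost: adjusted p = 0.698 for MYC target genes, adjusted p = 0.793 for G2/M-phase genes and adjusted p = 0.617 for each of the rest. No member of the 10 lists passed over all genes or adjusted over the list alone. The fixed replicate block ended the calls of MYC target genes, extracellular matrix and TGF-beta response genes, microglia and macrophage markers and ependymal and choroid plexus markers, and added S-phase genes (median 0.08). Without 129 female vector 1(3), G2/M-phase genes (median 0.00, camera adjusted p = 0.569) and MYC target genes (camera adjusted p = 0.209) were not called. The call of p53 target genes was lost without the array labelled B6 female vector 5.1(1) (camera adjusted p = 0.112).

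The other 14 lists were not called in this comparison. Their medians were 0.05 for S-phase genes, -0.04 for senescence-associated genes, -0.02 for growth factor and ERK-response genes, -0.02 for hypoxia and glycolysis genes, -0.03 for unfolded protein and ATF4 response genes, 0.10 for neural progenitor genes, -0.37 for Y-linked genes and 0.05 for X-linked genes escaping X inactivation. Among cell types the medians were 0.15 for astrocyte, 0.10 for oligodendrocyte lineage, 0.06 for neuron, 0.03 for fibroblast and meningeal, -0.23 for pericyte and smooth muscle, and -0.32 for endothelial markers.

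In 129 females, Dnah11 (4.88 ± 0.986) and Cdca7l (4.75 ± 1.03) had the smallest p-values, with adjusted p = 0.59 for each. Kdm5b, a histone H3K4 demethylase, lay at 2.03 ± 0.492 and the cytokine Il17a was at least 2.12-fold and the helicase Pif1 at least 1.4-fold lower, none past the threshold. MYC target genes lay lower (8 of 36 positive, median -0.13), as did extracellular matrix and TGF-beta response genes (6 of 23, -0.16), and interferon response genes lay higher (24 of 26, 0.39). Each of these camera calls was lost with an estimated correlation (adjusted p = 0.932). In limma 0 probe sets passed and 503 had an unadjusted p under 0.05. Without 129 female vector 4(1), 2(1) or 2(3), 1 probe set passed. Without 129 female vector 1(3), MYC target genes were not called (camera adjusted p = 0.179), and G2/M-phase genes (median -1.18), S-phase genes (-0.46), p53 target genes (0.15), antigen presentation genes (0.45), astrocyte markers (0.52) and ependymal and choroid plexus markers (1.02) were. None of the 3 calls was kept with each array left out in turn.

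In 129 males, markers of microglia and macrophages, the resident and infiltrating phagocytes of brain tissue, lay lower with Cdca7l: 0 of 14 members were positive, with a median of -2.22. It was -1.26 without 129 male vector 5(2) and -1.48 without 129 male vector 3(2), with mean shifts of -1.28 and -1.52 against -2.06 over all arrays of the microglia and macrophage list. The phosphatase Ptprc lay at -2.18 ± 0.793, the complement component C1qc at -2.05 ± 0.747 and the receptor Csf1r at -2.37 ± 1.02. The camera call (adjusted p = 1.31e-10) was lost with an estimated correlation (adjusted p = 0.191, but 0.00517 without 129 male vector 3(3)), and no member passed over all genes or adjusted over the list alone. G2/M-phase genes lay higher (24 of 27, median 0.66; adjusted p = 0.931 with an estimated correlation). The list named Cdca7l, MYC network and partners rose (16 of 20, median 0.11, adjusted p = 0.0113 with an estimated correlation), but the latter was 0.102 without 129 male Cdca7l 5(1), 0.0612 without 129 male vector 3(1) and 0.0538 with Cdca7l left out of the list.

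Camera calls in 129 males that were lost with an estimated correlation also covered interferon response genes (median -0.36), extracellular matrix and TGF-beta response genes (-0.36), astrocyte markers (0.21) and ependymal and choroid plexus markers (0.54), with adjusted p = 0.952, 0.931, 0.952 and 0.931 with an estimated correlation in that order. Without 129 male vector 3(3) Interferon response genes passed with an estimated correlation (adjusted p = 0.0343). Dnah11 (4.20 ± 0.882), Cdca7l (3.87 ± 0.925) and Dusp28, a dual-specificity phosphatase family member (-2.57 ± 0.633, above background on 1 of 5 Cdca7l arrays), had the smallest p-values, followed by Nckap1l, a blood-cell cytoskeletal regulator (-1.99 ± 0.552), and Susd2 (-1.12 ± 0.316), each with adjusted p = 1. In limma 0 probe sets passed and 422 had an unadjusted p under 0.05. Without 129 male Cdca7l 3(2) or 129 male vector 3(2) the count was 1, and without 129 female vector 1(3) it was 1.

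In B6 females, G2/M-phase genes lay higher with Cdca7l (27 of 27, median 0.80), with the proliferation marker Mki67 at 2.01 ± 1.47, and so did S-phase genes (23 of 25, 0.28). Microglia and macrophage markers lay lower (1 of 14 positive, median -1.33) and cholesterol synthesis genes did too (1 of 16, -0.21). Adjusted p-values with an estimated correlation were 0.896, 0.963, 0.186 and 0.395 in that order, so that none of these calls held. Camera also called Cdca7l, the MYC network and its partners (median 0.15), Y-linked genes (-1.08), X-linked genes escaping X inactivation (0.23), astrocyte markers (0.32), ependymal and choroid plexus markers (0.86) and extracellular matrix and TGF-beta response genes (-0.14), all lost with an estimated correlation (smallest adjusted p = 0.186). Without B6 female vector 2.1(1), Y-linked genes passed with it (adjusted p = 0.0342). With Cdca7l left out, the first of these lists was no longer called (camera adjusted p = 0.413). The group holds the array labelled B6 female vector 5.1(1), whose microglia and macrophage score of 3.86 was the highest of its group. Without it the median of that list was -0.44 and its mean shift -0.72 instead of -1.53 (camera adjusted p = 0.0422). Without B6 female vector 2.1(1), with a score of 3.08, the mean shift was -0.91, and without B6 female vector 3(3) the median was -2.05. Without the array labelled B6 female vector 5.1(1) the median of Y-linked genes was -0.04 and their call was lost (camera adjusted p = 0.741), and that of X-linked genes escaping X inactivation was 0.19 (camera adjusted p = 0.0462). The calls of cholesterol synthesis genes (camera adjusted p = 0.335) and of extracellular matrix and TGF-beta response genes (camera adjusted p = 0.172) were lost without it too.

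Dnah11 (5.29 ± 0.935, adjusted p = 0.0833) and Cdca7l (5.10 ± 0.981, adjusted p = 0.157) led the B6 female comparison, ahead of the acetyltransferase Nat1, at least 1.5-fold higher, the nuclear receptor Esrrg (1.82 ± 0.622) and the zinc-finger gene Zfp3 (0.68 ± 0.245), each of the latter with adjusted p = 1. In limma 0 probe sets passed and 142 had an unadjusted p under 0.05. With the clone label as a random replicate block Dnah11 passed as 1 probe set (adjusted p = 0.0076), and with a fixed replicate block 0 did. The fixed replicate block, which uses paired arrays alone, turned the median of microglia and macrophage markers from -1.33 to 0.24 (camera adjusted p = 0.00436; adjusted p = 0.442 with an estimated correlation), and of the other lists it lost 7 calls and gained 6. Without B6 female Cdca7l 4(5) the count was 1, and without 129 female vector 1(3) it was 2.

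In B6 males, inflammatory and antiviral genes lay higher with Cdca7l. NF-kB and inflammatory genes rose as a list: 19 of 20 members were higher, with a median of 0.77 (camera adjusted p = 2.52e-17; adjusted p = 0.00322 with an estimated correlation; fry adjusted p = 0.0605). The chemokine Ccl2 lay at 2.15 ± 0.713, the acute-phase protein Saa3 at 3.65 ± 1.28, the iron-siderophore binder Lcn2 at 2.14 ± 0.75 and the chemokine Ccl5 at 3.54 ± 1.34, and 0 members passed over all genes or adjusted over the list alone. With the replicate block the median was 0.88 and the call was lost with an estimated correlation (adjusted p = 0.197). Leaving out each array of the group in turn gave adjusted p between 0.00175 and 0.0449 with an estimated correlation. Of the 45 sets of 2 arrays left out, 7 ended that call, and without vector 5.6(1) and 2(2) the median was 0.27, with adjusted p = 0.412.

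Interferon response genes lay higher in B6 males for 25 of 26 members, with a median of 1.10 and adjusted p = 0.0631 with an estimated correlation; the antiviral synthetase Oas1a lay at 2.74 ± 0.903 and Usp18, an ISG15 protease, at 1.19 ± 0.485. Antigen presentation genes (10 of 10, median 0.50; adjusted p = 0.0985 with an estimated correlation) and senescence-associated genes (12 of 14, 0.17; adjusted p = 0.0631 with an estimated correlation) were also higher. Microglia and macrophage markers moved in the same direction (14 of 14, median 0.82; adjusted p = 0.85 with an estimated correlation), with a mean score of -0.18 in Cdca7l and -1.04 in vector arrays. The microglia and macrophage call was lost without B6 male Cdca7l 5.6(1) (median 0.34, camera adjusted p = 0.534), Cdca7l 2(2) (0.39, camera adjusted p = 0.444), vector 4(3) (1.00, camera adjusted p = 0.0527) or vector 2(4) (0.79, camera adjusted p = 0.174), and the median was 1.28 without Cdca7l 5(3) and 1.38 without Cdca7l 4(3). Camera further called Cdca7l, the MYC network and its partners (median 0.13; adjusted p = 0.0524 with an estimated correlation; camera adjusted p = 0.0551 with Cdca7l left out), p53 target genes (0.13; adjusted p = 0.85 with an estimated correlation), growth factor and ERK-response genes (0.22; 0.85), cholesterol synthesis genes (-0.15; 0.85) and extracellular matrix and TGF-beta response genes (0.10; 0.912). The replicate block removed the calls of Cdca7l, the MYC network and its partners, p53 target genes, growth factor and ERK-response genes and cholesterol synthesis genes, and added none. With an estimated correlation the list named Cdca7l, MYC network and partners passed without B6 male Cdca7l 5.6(1) (adjusted p = 0.0494), Cdca7l 2(2) (adjusted p = 0.0353) or vector 2(4) (adjusted p = 0.0273).

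**Figure D2:**
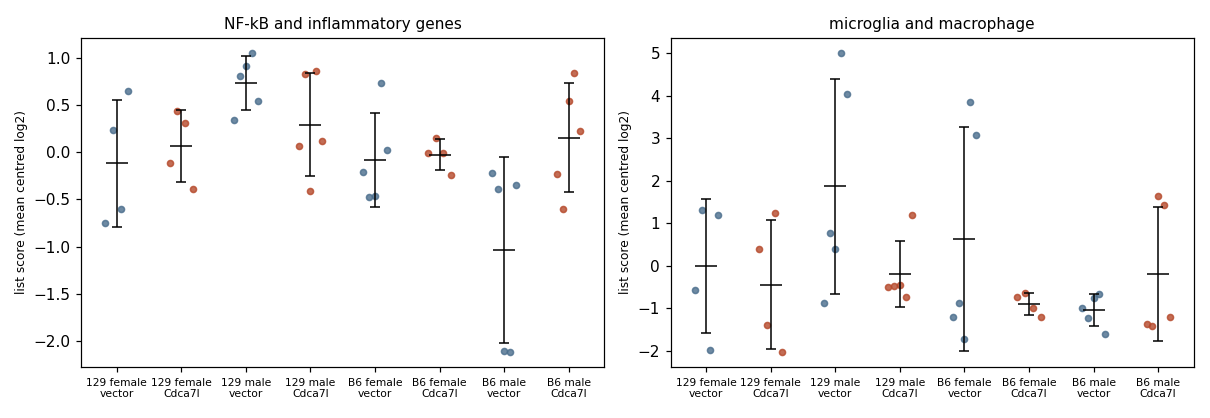
Scores of the NF-kB and inflammatory genes (left) and of the microglia and macrophage markers (right) on each array by group, as means of log2 values centred on each gene's mean over all arrays; points are arrays and the bar with whiskers is the group mean and SD. The B6 male vector arrays average -1.04 for the NF-kB list, against 0.16 with Cdca7l.

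Dnah11 (4.54 ± 0.882), Cdca7l (4.74 ± 0.925) and Mapk4, an atypical MAP kinase near background (at least 1.03-fold lower), had the smallest p-values in B6 males, with adjusted p = 0.19, 0.19 and 0.261. Next, with adjusted p = 1, were 9430021M05Rik, at least 2.73-fold higher, and Ttc30a2, an intraflagellar transport gene (2.80 ± 0.804). In limma 0 probe sets passed and 538 had an unadjusted p under 0.05. With a random replicate block 4 probe sets passed, those of Dnah11, Cdca7l, Mapk4 and Nfx1, a transcriptional repressor (1.28 ± 0.227), each with adjusted p = 0.024; with a fixed replicate block 0 did. Without B6 male vector 4(3) the count was 3, without B6 male Cdca7l 3(5) it was 1 and without 129 female vector 1(3) it was 2.

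The difference of the Cdca7l effect between sexes, between strains and between sexes across strains was tested for every gene, which addresses whether male and female astrocytes of either strain answer Cdca7l differently. Cdca7l itself differed by -0.61 ± 0.967 (males minus females), by -0.61 ± 0.967 (129 minus B6) and by -0.52 ± 1.93 in the strain by sex comparison, none past the threshold. In limma 0 probe sets passed in any of these comparisons, with 184, 429 and 188 at an unadjusted p under 0.05 and a smallest adjusted p of 1 in each. By chance alone 1279 would have such a p. Of simulated changes of 1 on the log2 scale, 10.4%, 20.9% and 4.48% were called, so counts of 0 do not show that the groups answer alike. The smallest p-values for sex belonged to Ttc30a2 (2.73 ± 0.841), the chromatin remodeller Srcap (0.44 ± 0.148), Zfp956 (-1.20 ± 0.418), Il17a (0.96 ± 0.343) and the transcription factor Tfap2c (1.99 ± 0.748). For strain they belonged to Gm7008 (-0.85 ± 0.255), Susd2 (-1.04 ± 0.330), the mRNA export factor Thoc2 (1.00 ± 0.331), the Golgi protein Golga1 (1.01 ± 0.343) and Zfp324 (-1.10 ± 0.391). For strain by sex they belonged to 5730409E04Rik (-2.09 ± 0.719), the TNF receptor Tnfrsf1b (-3.53 ± 1.21), Dcun1d3 (-1.27 ± 0.438), the deadenylase subunit Pan2 (2.68 ± 0.967) and Angel1 (-1.40 ± 0.508).

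Among lists, the Cdca7l effect on NF-kB and inflammatory genes lay higher in males than females (18 of 20, median 0.30) and lower in 129 than B6 (1 of 20 positive, median -0.51). Adjusted p-values with an estimated correlation were 0.894 and 0.428. In the strain by sex comparison, interferon response genes (0 of 26 positive, median -1.51), NF-kB and inflammatory genes (0 of 20, -1.22) and microglia and macrophage markers (0 of 14, -3.67) lay lower together, each with adjusted p = 0.114 with an estimated correlation. Interferon response genes passed with it there without 129 male vector 3(3) (adjusted p = 0.0248). G2/M-phase genes lay higher there (26 of 27, 1.33; adjusted p = 0.664 with an estimated correlation).

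Among vector astrocytes, the Y-linked genes Eif2s3y, a translation initiation factor subunit, Kdm5d, a histone demethylase, and Uty were higher in males, and Xist, the RNA that silences the inactive X chromosome, was higher in females. The differences were 8.97 ± 0.714 for Eif2s3y, 6.51 ± 0.561 for Kdm5d and 3.50 ± 0.326 for Uty (males minus females, n = 10 and 9), with adjusted p = 2.76e-09, 4.19e-09 and 2.36e-08. With values below background raised to it, they were 8.30, 6.16 and 3.16. Xist was at least 177-fold lower in males (adjusted p = 2.76e-09). The female group includes the array labelled B6 female vector 5.1(1), the only female array with Eif2s3y above background. Without that array Eif2s3y was at least 579-fold higher, Kdm5d differed by 7.24 and Xist was at least 330-fold lower. The histone demethylase Kdm5b (1.63 ± 0.321, adjusted p = 0.0309), the adhesion receptor Adgra1 (1.56 ± 0.308, adjusted p = 0.0309) and the neural transcription factor Zic2 (1.43 ± 0.276, adjusted p = 0.0255) were also higher in males. Each of these 3 fell short without 129 female vector 1(3), with adjusted p = 0.0652, 0.0652 and 0.0573, and after repeated quantile normalization, with adjusted p = 0.0805, 0.0805 and 0.114. Kdm5b and Adgra1 each had 2 other tested probe sets, none of which passed. The sex difference of Kdm5b was larger in 129 than in B6 cells by 3.11 ± 0.642 (adjusted p = 0.176). Mean Kdm5b was 7.22 in 129 female vector arrays, against 9.14 over female and 10.77 over male vector arrays. By these fitted means nearly all of its averaged difference came from 129 cells.

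The Y-linked list rose with male sex, with 3 of 4 measured members past the threshold over all genes and 3 adjusted over the list alone, and adjusted p = 5.85e-05 with an estimated correlation; Uba1y was above background on 2 of 10 male and 0 of 9 female arrays. X-linked genes escaping X inactivation fell in males relative to females: 1 of 9 members passed over all genes and 3 adjusted over the list alone, namely Xist, the histone demethylase Kdm6a (-0.80 ± 0.217) and 5530601H04Rik (-0.92 ± 0.310), with adjusted p = 0.000269 for the list with an estimated correlation. Camera calls lost with an estimated correlation were those of MYC target genes (6 of 36 positive, median -0.25; adjusted p = 0.638), S-phase genes (6 of 25, -0.20; 0.906), G2/M-phase genes (6 of 27, -0.59; 0.906), cholesterol synthesis genes (14 of 16, 0.26; 0.906) and astrocyte markers (22 of 23, 0.74; 0.906). Of these, 2 cholesterol synthesis genes were past the threshold adjusted over the list alone and 0 over all genes.

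**Figure D3:**
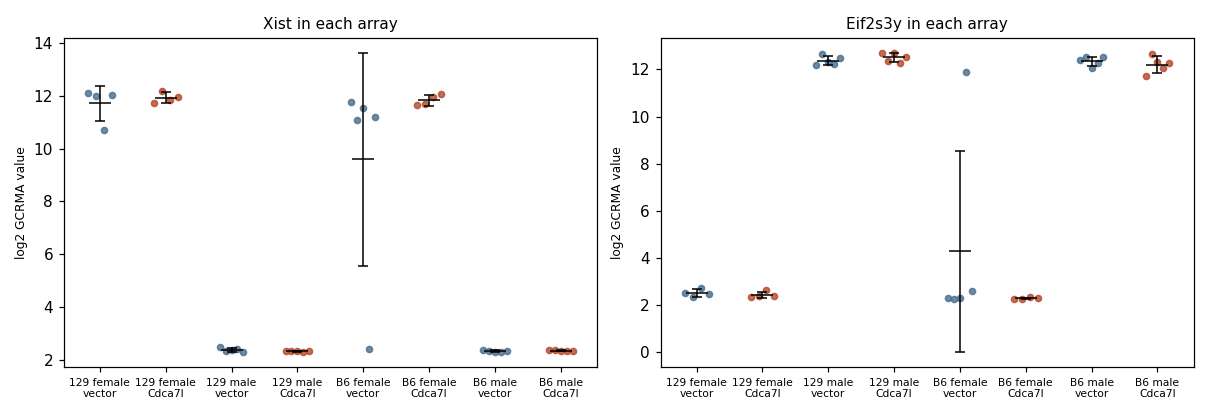
Log2 GCRMA values of Xist (left) and Eif2s3y (right) on each array by strain, sex and plasmid; points are arrays and the bar with whiskers is the group mean and SD. One array labelled B6 female vector has Xist at 2.40 and Eif2s3y at 11.91.

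In all, 16 probe sets passed for sex in vector astrocytes, 12 higher and 4 lower in males; 7 genes passed on the probe set with their highest mean. Ccnc, a cyclin, was lower in males on another of its probe sets (adjusted p = 0.0142). Leaving out both arrays that stand apart gave 31, of which 15 were among the 16. Leaving out the array labelled B6 female vector 5.1(1) alone gave 24, which held all 16. The count was 9 without 129 female vector 4(1), 10 without B6 female vector 6(3) or 4(5), 31 without B6 male vector 3(5) and 35 without 129 female vector 2(3).

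Far more probe sets passed between the strains of vector astrocytes (2420) than between their sexes (16). Without the array labelled B6 female vector 5.1(1) these counts were 2004 and 24. Of the 2420, 823 were higher and 1597 lower in 129. Probe sets over bases that differ between strains can add to the strain count, and they were not told apart from differences in RNA. Between Cdca7l and vector arrays 2 passed in the averaged comparison. Interferon-inducible Ifi202b was at least 548-fold higher in 129 than in B6 cells (adjusted p = 4.13e-25, n = 9 and 10), and the guanylate-binding gene Gbp2b was at least 124-fold higher. Crct1 (6.74 ± 1.40), Mgp, an inhibitor of calcification (6.41 ± 1.47), the fibrillar collagen Col3a1, at least 44-fold higher, and the branched-chain aminotransferase Bcat1 (5.97 ± 0.888) came next. Grem1, a BMP antagonist (5.70 ± 1.54), thrombomodulin Thbd (5.30 ± 1.30) and the chromatin protein Hmga2 (5.25 ± 1.29) were also among the largest positive differences. Mgp and Grem1 were above background on 1 of 10 B6 arrays each, for Mgp the array labelled B6 female vector 5.1(1), without which Mgp was at least 86.8-fold higher. Crct1 was above it on 3 of 10. With values below background raised to it, Mgp differed by 5.705, Grem1 by 5.09 and Crct1 by 6.63. Col3a1 was at least 72.5-fold higher without 129 female vector 1(3) and at least 79.8-fold without 129 male vector 3(2). Without 129 female vector 1(3) the differences were also larger for Crct1 (7.415), Mgp (7.42), Thbd (6.19) and Hmga2 (5.85), and the fold of Grem1 was 1.75 times that over all arrays. Without B6 female vector 2.1(1) Crct1 differed by 7.38 and Hmga2 by 5.86. The difference of Grem1 was 4.98 without 129 female vector 4(1) and 5.00 without 129 female vector 2(1).

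Lower in 129 cells were 2 members of the antiviral TRIM family, Trim12a (-7.99 ± 0.162) and Trim30d (-7.13 ± 0.299). Elobl (-8.81 ± 0.608), the centrosomal gene Cep85 (-8.58 ± 0.391) and the zinc-finger gene Zfp874a (-7.58 ± 0.203) also fell, while 2610507I01Rik was at least 17.8-fold and Mocs1, of molybdenum cofactor synthesis, at least 18.8-fold lower. Trim12a and Zfp874a were above background on 1 of 9 129 arrays each, and with values below background raised to it they differed by -7.44 and -7.10. Sugct (-5.00 ± 0.249; -4.81 with raised values), the galactosyltransferase B3galt6 (-4.98 ± 0.505) and Mro (-4.85 ± 0.430) were lower as well. A single probe set stands for Ifi202b, Gbp2b, Crct1, Mgp, Grem1, Thbd, Elobl, Trim12a, Zfp874a, Mocs1 and Mro, no other tested probe set of Cep85, 2610507I01Rik, Sugct or Bcat1 passed, and probe sets can lie over bases that differ between strains, which these values do not show.

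**Figure D4:**
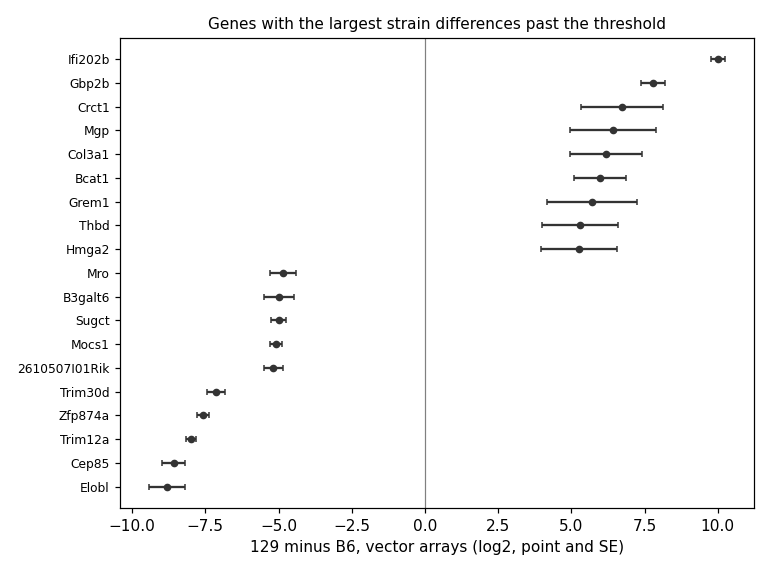
Differences between 129 and B6 vector arrays on the log2 scale for genes with the largest differences past the threshold; points are fitted differences and whiskers are SE. They run from -8.81 for Elobl to 10.00 for Ifi202b, where values at background make the difference of some genes a bound.

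Extracellular matrix and TGF-beta response genes were higher in 129 cells, with 7 of 23 members past the threshold over all genes and 10 adjusted over the list alone (median 0.78; fry adjusted p = 0.0103). The collagens Col1a1 (3.45 ± 0.859), Col1a2 (3.02 ± 0.630), Col6a2 (3.44 ± 0.730) and Col5a1 (1.06 ± 0.219) were among them. Of senescence-associated genes, 3 rose over all genes (6 rose and 2 fell adjusted over the list alone): the protease inhibitor Timp1 (1.92 ± 0.435), the chemokine Cxcl1 (1.02 ± 0.206) and the collagenase Mmp13, at least 3.78-fold higher (fry adjusted p = 0.0103), though Mmp13 reached only adjusted p = 0.0641 without the array labelled B6 female vector 5.1(1). Fibroblast and meningeal markers had 4 higher and 1 lower member over all genes and the same numbers adjusted over the list alone, with a median of 1.06. Each of these 3 camera calls was lost with an estimated correlation (adjusted p = 0.6). Col1a1, Col1a2 and Col3a1 belong to both the matrix and the fibroblast list, so these calls are not separate. Mean fibroblast scores were 0.144 in female and 1.59 in male 129 vector arrays, against -0.593 and -1.1 in B6. The values do not show which cells of a culture carried these RNAs. The 1 other tested probe set of Col6a2 did not pass.

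Antigen presentation genes were lower in 129 cells, with 0 of 10 positive and a median of -0.63. H2-M3 (-1.21 ± 0.290) and the class I gene H2-K1 (-0.76 ± 0.226) fell over all genes, and 4 members adjusted over the list alone (fry adjusted p = 0.0457; camera adjusted p = 0.6 with an estimated correlation). Astrocyte markers lay lower (0 of 23 positive, median -0.85; adjusted p = 0.675 with an estimated correlation), with the bicarbonate transporter Slc4a4 (-1.13 ± 0.302) past the threshold over all genes and 4 members adjusted over the list alone. Microglia and macrophage markers lay higher (12 of 14, median 0.92; adjusted p = 0.713 with an estimated correlation), with the tetraspanin Cd53 (4.67 ± 1.17) past the threshold in both ways. Cd53 differed by 5.285 without B6 female vector 2.1(1). Cell-cycle lists lay higher too: S-phase genes (23 of 25, median 0.62; adjusted p = 0.63 with an estimated correlation) with the licensing factor Cdt1 (1.40 ± 0.437), the helicase subunit Mcm3 (1.30 ± 0.403) and Fen1 (0.57 ± 0.187) past the threshold over all genes and adjusted over the list alone, and G2/M-phase genes (26 of 27, 0.99; adjusted p = 0.713 with an estimated correlation). Without the array labelled B6 female vector 5.1(1), Cdt1 (adjusted p = 0.0554) and Fen1 (adjusted p = 0.0699) fell short, as did Fen1 without 129 female vector 1(3) (adjusted p = 0.0549). The call of microglia and macrophage markers was also lost without the latter (camera adjusted p = 0.0518). None of the 4 other tested probe sets of Mcm3 passed, nor did the 1 other of Fen1, while the 1 other of Cdt1 did.

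MYC target genes lay higher in 129 cells (33 of 36, median 0.32; adjusted p = 0.6 with an estimated correlation), with 2 members up and 1 down both over all genes and adjusted over the list alone: the nucleolar genes Noc4l (0.69 ± 0.190) and Mybbp1a (0.62 ± 0.182) and, lower, the folate enzyme Shmt1 (-1.24 ± 0.325; adjusted p = 0.0601 after repeated quantile normalization). NF-kB and inflammatory genes lay higher (16 of 20, 0.46; adjusted p = 0.6 with an estimated correlation), with 2 rising over all genes, Cxcl1 and Saa3 (3.28 ± 0.936), and 3 adjusted over the list alone. Without 129 female vector 1(3) the list was not called (camera adjusted p = 0.0616). Saa3 differed by 2.66 without B6 male vector 5.6(1) and by 2.65 without B6 male vector 2(2). In the p53 target list (4 of 20 positive, -0.26; adjusted p = 0.63 with an estimated correlation) 3 fell over all genes and 8 adjusted over the list alone, the death receptors Tnfrsf10b (-1.57 ± 0.291) and Fas (-0.74 ± 0.240) and the exonuclease Aen (-0.36 ± 0.115). Without the array labelled B6 female vector 5.1(1), Fas (adjusted p = 0.0544) and Aen (adjusted p = 0.0511) fell short. No other tested probe set of Mybbp1a, Shmt1 or Tnfrsf10b passed, while 1 of 3 others passed for Noc4l and for Aen.

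Lists without a camera call held single genes past the threshold. Higher in 129 cells were the chromatin helicase Hells (1.83 ± 0.581), the ERK-response genes Phlda1 (0.95 ± 0.265) and Fosl1 (3.17 ± 0.997), and the synaptic vesicle gene Syt1 (2.83 ± 0.453). Lower were the immediate-early factor Fos (-2.14 ± 0.559), the immunoproteasome subunit Psmb9 (-1.69 ± 0.508), Sel1l, of protein quality control (-0.30 ± 0.083), the progenitor factor Sox1 (-1.24 ± 0.295), the neuronal cytoskeletal gene Map2 (-1.04 ± 0.301), the receptor Notch3 (-1.16 ± 0.353), Ccdc153 (-2.57 ± 0.842) and Mid1, at least 6.4-fold lower. Without the array labelled B6 female vector 5.1(1), Hells (adjusted p = 0.0775) and Fosl1 (adjusted p = 0.0711) fell short, and without 129 female vector 1(3) Map2 (adjusted p = 0.0564) and Ccdc153 (adjusted p = 0.0567) did. Notch3 fell short after repeated quantile normalization (adjusted p = 0.0536). Fosl1 differed by 3.78 without B6 male vector 4(3). Hells did not pass adjusted over its list alone. No other tested probe set of Hells, Map2 or Sel1l passed. With values below background raised to it, Syt1 differed by 2.41 and Ccdc153 by -2.22. Xaf1, an interferon-induced gene, lay at -1.85 ± 0.428 on 1 probe set and passed in the opposite direction on another.

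Strain difference in vector astrocytes gave 2420 probe sets past the threshold, 823 higher and 1597 lower in 129. On the probe set with the highest mean of each gene with a single symbol, 1233 genes passed, 415 higher and 818 lower. The count was 1498 without 129 female vector 4(1) and 1608 without B6 female vector 3(3). Strain by sex in vector cells gave 0 probe sets in limma, with 2501 at an unadjusted p under 0.05 and a smallest adjusted p of 0.176, held by Kdm5b (3.11 ± 0.642), 5730409E04Rik (2.43 ± 0.501) Ccn5, a matricellular protein (2.39 ± 0.519), Faf2 (0.97 ± 0.212) and 1110002L01Rik (3.44 ± 0.755). Leaving out 129 female vector 2(1) or B6 male vector 4(3) gave 1 probe set, and leaving out 129 male vector 3(3) gave 2. Interferon response genes were positive in this comparison for 26 of 26 members (median 1.74; adjusted p = 0.387 with an estimated correlation), with 4 past the threshold adjusted over the list alone and 0 over all genes.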

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

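The counts over other splits of the arrays were planned; the tests of the sex-mismatched array, of Dnah11 and of the NF-kB list were chosen after the results were seen.

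The array labelled B6 female vector 5.1(1) stood far from its group for Eif2s3y (11.91), Kdm5d (10.02), Uty (5.83) and Xist (2.40). The 3 Y-linked genes lay at 81% or more of the way from the female to the male mean. A mixture of female and male cells would keep Xist above the male arrays, but it lay at -0.0978 relative to the highest male array. A swap inside the series would need a male-labelled array with Xist above background, and 0 of 20 had it. A single culture or array of male origin under a female label may account for these values, and no biological explanation was tested.

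Dnah11 and Cdca7l, whose annotated spans overlap, moved together beyond the plasmid. Deviations from the group means correlated at r = 0.897 over the 19 vector arrays (two-sided permutation p = 1e-05, the smallest the resampling can give; Spearman rho = 0.849, permutation p = 2e-05; r = 0.873 without the 2 arrays farthest from the median) and at r = 0.997 over the 18 Cdca7l arrays (rho = 0.99, both two-sided permutation p = 1e-05; r = 0.996 without 2), 2 relations in all. Vector arrays hold no Cdca7l plasmid, so their value shows a relation that is present without it. It cannot test whether RNA of the plasmid raised both probe sets in the Cdca7l arrays. A shared or overlapping RNA read by both probe sets may account for the relation. A Dnah11 gene that answers the cell's own Cdca7l would give the same correlation and stays open.

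NF-kB and inflammatory genes lay higher with Cdca7l in B6 males, where vector arrays 5.6(1) and 2(2) had scores of -2.11 and -2.12 and the other vector arrays lay between -0.394 and -0.216; without these 2 arrays, 1 of 45 sets of 2 left out, 39.7% of the mean shift was left, the lowest share of all sets. With the microglia and macrophage score as a term of the fit 90.3% was left (1.19 ± 0.364 before and 1.08 ± 0.345 after, SE). The term had 1 slope over all 37 arrays and did not use the pairs. In pairs 5.6(1) and 2(2) the microglia and macrophage score was 1.63 and 1.44 with Cdca7l, against -0.753 and -0.658 with vector. It was -1.19 against -1.6 in pair 3(5) and -1.42 against -0.986 in pair 4(3). In each pair it moved in the direction of the NF-kB score, so the term cannot decide whether these cells were the source. Actin 3' minus 5' values averaged 1.69 in Cdca7l and 1.38 in vector arrays. With them as a term 97.2% was left, and 95% with those of Gapdh (1.13 ± 0.375, SE). These terms too had 1 slope over all arrays. With Cdca7l against vector, actin lay at 1.99 against 1.48 in pair 5.6(1) and 1.92 against 1.395 in 2(2). It lay at 1.49 against 1.03 in 4(3) and 1.09 against 1.43 in 3(5). The terms therefore cannot decide on RNA integrity either. Over the 252 splits of the 10 arrays the exact two-sided permutation p was 0.0635, and the 4 pairs differed by 2.65 for 5.6(1), 2.96 for 2(2), 0.566 for 3(5) and -0.382 for 4(3) (exact two-sided p = 0.25, where 0.125 is the smallest possible). The pairs with the largest NF-kB differences had the smallest rises of Cdca7l. Cdca7l lay at 10.15 against 8.17 in 5.6(1) and 11.38 against 8.75 in 2(2). It lay at 12.75 against 9.07 in 4(3) and 14.39 against 4.12 in 3(5). Over these few pairs the shift did not follow the size of the Cdca7l rise, a relation that was not tested. Chance in the split may account for the shift, and an effect of Cdca7l in cells of this sex and strain stays open.

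Of 180 group values tested, 25 had a sample far from the rest, where chance gives about 1 in 20. Apart from the sex-mismatched array's values above, 129 female vector 1(3) had Xist at 10.71, Crct1 at 7.15, Thbd at 3.07, Trim12a at 3.49, 2610507I01Rik at 2.83, Mro at 6.56 and an upper quartile of 8.36. B6 male vector 4(3) had Crct1 at 7.72, Grem1 at 5.85, Hmga2 at 10.88, Elobl at 8.42 and B3galt6 at 11.66, and B6 male vector 3(5) had Cdca7l at 4.12 and Col3a1 at 2.62. The array labelled B6 female vector 5.1(1) also had Mgp at 11.36, and B6 female vector 3(3) had Dnah11 at 8.23. Among the 129 males, vector 3(3) had Ifi202b at 11.01 and Mocs1 at 2.55, vector 5(2) had an S-phase score of 0.87, Cdca7l 5(1) had Kdm5d at 10.21 and Cdca7l 3(2) had a microglia and macrophage score of 1.20. The values of Col3a1, Mocs1 and 2610507I01Rik lay below the background level of 3.189 with the rest of their groups. The chance share assumes normal values, and several of the values came from the same arrays.

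Camera's preset test of a difference between groups passed for 28 list shifts, none of them with an estimated correlation. Between sexes, the Cdca7l effect differed by a median of 0.0548 for MYC target genes, 0.297 for NF-kB and inflammatory genes, 0.109 for extracellular matrix and TGF-beta response genes and 0.513 for Y-linked genes, the last being 0.038 (camera adjusted p = 0.641) without the array labelled B6 female vector 5.1(1). Between strains it differed by -0.20 for S-phase genes, -0.294 for senescence-associated genes, -0.412 for interferon response genes, -0.514 for NF-kB and inflammatory genes, -0.28 for extracellular matrix genes and -0.90 for microglia and macrophage markers. For strain by sex it was 1.33 for G2/M-phase genes, -0.714 for senescence-associated genes, -1.51 for interferon response genes, -1.22 for NF-kB and inflammatory genes, -0.558 for antigen presentation genes, 0.552 for X-linked genes escaping X inactivation and -3.67 for microglia and macrophage markers. In vector cells the strain by sex medians were -0.49 for MYC target genes, -0.371 for S-phase genes, -0.634 for G2/M-phase genes, 0.334 for p53 target genes, 1.74 for interferon response genes, 1.01 for NF-kB and inflammatory genes, 1.06 for antigen presentation genes, 0.875 for extracellular matrix genes, -0.378 for X-linked genes escaping X inactivation, 3.51 for microglia and macrophage markers and 1.5 for fibroblast and meningeal markers.

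For strain in vector cells, 1 of 100 splits, the real one, reached 2420 probe sets and the highest other gave 561. For sex in vector cells, 2 of 100 reached 16, the real one among them, and the highest other gave 188. Such counts were rare among the splits. The splits treat the arrays as independent, although those sharing the number in parentheses resembled each other, so chance is not excluded. For the averaged Cdca7l effect 5 of 100 splits reached the 2 probe sets of the real one and the highest other gave 610, so that this count does not exclude chance; the exact tests of Cdca7l in each group stand apart from it. Where the real count was 0, every split reached it: 35 of 35 in 129 females (highest other 7165), and 100 of 100 in 129 males (651), B6 females (286) and B6 males (974), for the sex (5), strain (0) and strain by sex (2804) differences of the effect, and for strain by sex in vector cells (3). Of the splits that part every pair, 0 of 23 in B6 females and 2 of 13 in B6 males called any probe set (at most 4), against 21 of 77 and 28 of 87 of the others (at most 286 and 974, median 0 in both), so that most splits of either kind called none and the source of the high counts was not settled.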

How the results depend on the processing

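Blocks, weights and filters were planned; the block on the number in parentheses, the gene-by-gene weights and the fits without the arrays 129 female vector 1(3) and B6 female vector 5.1(1) were chosen after seeing the data. Of the settings tried, array weights changed most counts. The planned default weights stopped before convergence and ran from 0.0357 to 10.1. They gave 3 probe sets in 129 females, 98 in 129 males, 73 in B6 females and 51 in B6 males for Cdca7l, 424 for sex, 5511 for strain and 295 for strain by sex in vector cells. Weights estimated gene by gene (0.105 to 7.92) gave 109, 1589, 51 and 217 for Cdca7l in the same groups, 2 and 267 for its sex and strain differences, and 7951, 12034 and 4267 in vector cells. The array 129 female vector 2(1) had the lowest default weight, 0.0357, but 5.35 gene by gene. The rest of its group had 0.105 to 0.703 gene by gene, so that group mean then rested largely on this array. Both weightings thus disagreed on it. The cause of the changed counts was not tested.

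The random replicate block gave 1 probe set in 129 females, 1 in B6 females and 4 in B6 males. The fixed replicate block left 1 in the averaged comparison, that of Dnah11 (adjusted p = 0.00976), with Cdca7l at 4.61 and adjusted p = 0.0688, and turned the microglia and macrophage median in B6 females to 0.243; unpaired arrays drop out of it, and it changed no other probe set count by over 1.5 times. Of same-labelled arrays, 4 of 8 in 129 females and 6 of 8 in 129 males lay closest to their own number. The clone number as a block gave 1 in B6 females, 10 for sex and 1286 for strain; the number in parentheses gave 9 and 1474 for the latter. The stricter filter gave 1 in B6 females, and 1 probe set per gene gave 1 there, 7 for sex and 1317 for strain, from fewer genes tested. Fits of the compared groups alone gave 2 in 129 males and 1 for strain by sex in vector cells. Without both arrays that stand apart there were 1 in 129 males, 1 in B6 females, 1 in B6 males and 31 for sex. The cause was not tested.

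With each array left out in turn, counts ran from 0 to 1 in 129 females, 0 to 1 in 129 males, 0 to 1 in B6 females and 0 to 3 in B6 males (3 without vector 4(3)), from 9 (without 129 female vector 4(1)) to 35 (without 129 female vector 2(3)) for sex, from 1498 (without 129 female vector 4(1)) to 3429 (without 129 female vector 1(3)) for strain and from 0 to 2 (without 129 male vector 3(3)) for strain by sex in vector cells. The averaged count stayed at 2 and the differences of the Cdca7l effect at 0 throughout. The Cdca7l difference stayed past an unadjusted 0.05 under every setting run for it, from 3.61 to 5.69 over groups and left-out arrays. List calls numbered 87 with the preset correlation, 5 with an estimated correlation and 6 with fry. The fixed replicate block moved them from 11 to 8 in the averaged comparison, from 7 to 3 in 129 males, from 10 to 9 in B6 females and from 10 to 6 in B6 males. Repeated quantile normalization and median centring moved the median of all probe sets by up to 0.225 and 0.187. Groups with every array at or below the background level of 3.189 give bounds only.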

Other observations

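The tests here were all chosen after results had been seen. Among the 19 vector arrays, which hold no Cdca7l plasmid, those with more of their own Cdca7l also expressed more S-phase genes. Deviations from the group means correlated at r = 0.825 (two-sided permutation p = 3e-05; Spearman rho = 0.775, permutation p = 0.00017), and r was 0.792 without the 2 arrays farthest from the median. These p-values treat the arrays as independent. The 129 female vector arrays had the widest spread, with an S-phase score SD of 1.41, against 0.38 to 0.427 in the other vector groups. Their Cdca7l SD was 2.81, against 0.559 to 2.04. The pooled correlation therefore rests largely on that group and does not show whether the relation holds in each group. Within the 6 pairs of vector arrays of a group that share the number in parentheses, both moved the same way in 3, and the differences correlated at 0.327 (exact two-sided p = 0.562). A larger share of dividing cells in cultures with more Cdca7l may account for the relation, but it cannot be told apart from a shared origin of the cultures, as so few pairs share a number.

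Arrays of 1 strain and sex resembled each other by the number in parentheses of the clone label. Over 21 pairs sharing that number alone, deviations from the group means correlated at a mean of 0.205, against -0.224 over 98 pairs sharing neither number, a difference of 0.429 (one-sided permutation p = 0.0013, adjusted p = 0.0026 over both numbers). The 20 pairs sharing the number before the parentheses alone averaged -0.331, a difference of -0.107 (one-sided permutation p = 0.847). The number in parentheses may mark cultures of shared origin, which the labels do not say.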
